A study of Homo sapiens with 7 samples.

How the data were processed

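Seq-Well, a method that captures single cells with barcoded beads in arrays of small wells, was used on cerebrospinal fluid (CSF) cells and on peripheral blood mononuclear cells. There were 7 libraries in 3 groups: HIV CSF (n = 3), HIV blood (n = 2) and uninfected CSF (n = 2). The donor numbers in the titles give 2 HIV donors with both fluids, and the group labels state HIV antibody status. The deposited values were raw counts per gene and cell barcode, with 5000 barcodes per library and 42496 gene names over 35000 barcodes. The submitters' processing notes name STAR and hg19 and give no version, counting program or annotation. The labels do not say whether the counts are molecular identifiers, so intervals and floors cover counting error only. The values were whole numbers with a different total per barcode, and no normalization was found. The GENCODE v29 annotation on GRCh38 and a RefSeq table served only for gene names and biotypes, and no coordinates were used. Gene symbols are those of the count tables, which use older names such as IL8, SEPP1 and IGJ.

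Barcodes with at least 300 genes detected and at most 20% of counts from mitochondrial genes were kept. Scrublet in scanpy 1.11.5 marked 19 barcodes as doublets and left 13767 cells. A marked share this low means that doublet removal is to be read as not having worked, and cells with transcripts of T cells and of myeloid cells were removed as an alternative. Such a cell held at least 2 counts of CD3D, CD3E, CD3G, CD2 and TRAC together and at least 2 counts of LYZ, FCN1, CD14, C1QA, C1QB, C1QC and S100A9 together. XIST, TSIX, Y-linked genes, variable segments of immunoglobulins and T-cell receptors, HLA-DRB3 to HLA-DRB6, GSTM1, GSTT1 and ERAP2 were left out of every sum and test, since their level follows a donor's sex, clones or genotype.

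Counts per cell were scaled and log-transformed, and 2000 variable protein-coding genes other than ribosomal genes gave 25 principal components. Clusters came from the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1 on a graph of 15 neighbours. The myeloid clusters were clustered a second time with 1000 variable genes, 15 components and resolution 0.5. A cluster took the class with the most markers among its 10 leading protein-coding genes, counted among genes detected in at least 10% of its cells and ranked by fold over all other kept cells. At least 3 markers of the class had to be detected, and a cluster with 3 or more markers of other lineages among the 10 stayed unnamed. The marker lists, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The naming rule, its limits and the second clustering were set after several looks at the clusters. The shares of unnamed cells per group are therefore given with the results. Myeloid-like cells were the monocyte-like, dendritic-like and microglia-like cells together, and no cluster was named after border macrophages, platelets, neural or glial cells, or epithelial or endothelial cells. Cell types carry the ending -like because RNA markers alone named them.

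Cells were not treated as replicates. Counts were summed per library over all kept cells, T-cell-like cells and myeloid-like cells, with at least 20 cells per sum. The sums held 955822 to 6308292 counts for all cells, 222822 to 4883219 for T-cell-like cells and 373098 to 1094765 for myeloid-like cells. The 7 sums of a class entered 1 edgeR 4.0.16 quasi-likelihood fit with 3 groups, TMM normalization and the filterByExpr filter, with Benjamini-Hochberg adjustment at 5%. Levels are TMM-normalised CPM, counts scaled to a common library size, as mean ± SD, and log2 fold changes are given ± SE. DESeq2 1.42.0 was run on the same sums. These p-values measure the spread between these samples. The contrasts were HIV CSF against HIV blood, and HIV CSF against uninfected CSF; both use the same HIV CSF libraries. The first contrast was repeated with donor number as a replicate block, on the libraries of that contrast alone. HIV CSF 3 has no blood library and stands alone in its block, so this fit rests on donors 1 and 2. It leaves fewer residual degrees of freedom than the main fit, which has 4. Calls gained with the block are therefore uncertain. Deviations were taken from the mean of libraries 1 and 2 of each group, without HIV CSF 3. Across genes they correlated at r = 0.108 between HIV CSF and HIV blood of the same number in all cells. The correlation was 0.0984 in T-cell-like cells and 0.083 in myeloid-like cells. The corresponding values for HIV CSF and uninfected CSF, whose numbers name different donors, were 0.158, 0.14 and 0.115, and genes are not independent replicates. The sign of these 0.158, 0.14 and 0.115 depends on how the uninfected donors were numbered, so they are no baseline for pairing.

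The 27 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with other genes. Fry tests whether a list moves on balance 1 way, and its mixed form whether members change in either direction; neither compares the list with other genes. The adjusted p of a list is over the lists of 1 contrast and class. Several lists share members with the markers that named the clusters, among them APOE, C1QB, S100A9 and CD79A. A second count of changed members was adjusted over the list alone. For HIV against uninfected CSF, the median of each called list was set against medians of 10000 random lists of protein-coding genes matched on level. The lists cover homeostatic and disease-associated microglia, complement, lipid and iron handling, border macrophages, MHC class II, classical and nonclassical monocytes, interferon-stimulated genes and inflammatory cytokines. They also cover naive T, T memory and migration, cytotoxic, T activation and exhaustion, and regulatory T genes, the cell cycle, immediate early and heat shock genes, HIV receptors and restriction factors, and oxidative phosphorylation. The remaining lists hold markers of B cells, monocytes, T cells, platelets, erythroid cells, neutrophils, and brain and barrier cells.

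The rule for genes named as changed took the 10 highest and 10 lowest fold changes among genes past 5% whose groups did not overlap and whose mean CPM was at least 50, plus at most 4 list members past 5% per list. Each such gene lay in all libraries of 1 group above all libraries of the other. List members that did not pass are given as examples with values. A group with 0 counts took a floor of 3 counts over the group, and 1 to 3 counts were given as a ratio of summed counts with its 95% counting interval. Genes with clone names, antisense genes and pseudogenes are reported as uncertain, since reads of related genes can be assigned to them.

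Shares of kept cells per library carry Clopper-Pearson 95% intervals, which cover counting error only. Group means were compared with a two-sided exact permutation test over 10 arrangements, whose smallest p is 0.1, so no share can reach 0.05. Levels in microglia-like cells are counts per 10000 counts of the class and were not tested. Background RNA was gauged by microglia genes in T-cell-like cells and in barcodes with at least 100 and under 300 genes. These microglia genes were C1QA, C1QB, C1QC, APOE, APOC1, TREM2, MSR1 and AXL, and none of them is on the homeostatic microglia list.

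The fits were tested on simulated data with the depths and spread of the real sums. A first version with 2-fold and 4-fold changes recovered close to none of them with edgeR, after which 16-fold changes and a second spread of counting error alone were added. With the real spread, edgeR recovered 81.0% of 16-fold, 29.7% of 4-fold and 1.67% of 2-fold changes for CSF against blood in all cells, among 16664 genes. The other contrast in all cells gave 74.6%, 7.81% and 0%. T-cell-like cells gave 81.2%, 24.6% and 0% for CSF against blood and 67.2%, 3.08% and 0% for HIV against uninfected, among 12681 genes. Myeloid-like cells gave 83.6%, 28.6% and 0%, and 75.4%, 27.0% and 0%, among 9644 genes. False edgeR calls in that order numbered 4 of 75, 4 of 56, 7 of 75 and 2 of 47. In myeloid-like cells they numbered 9 of 78 and 6 of 69. The false share of edgeR calls lay above the adjustment limit except for HIV against uninfected CSF in T-cell-like cells. Genes with an edgeR adjusted p close to that limit are therefore less certain. False DESeq2 calls numbered 46 of 144, 23 of 112, 30 of 122 and 23 of 94. In myeloid-like cells those of DESeq2 numbered 19 of 98 and 11 of 93. DESeq2 counts are therefore less strict than edgeR counts. With counting error alone, edgeR recovered between 34.3% and 82.1% of 2-fold changes.

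The choices fixed at the start to be changed 1 at a time were no gene filter, size factors of DESeq2 in edgeR, DESeq2, only the compared groups, the replicate block, counts thinned to equal depth, at least 500 or 200 genes per cell, no mitochondrial limit, doublets kept, classes from each cell's own markers, other cluster resolutions, and each library left out in turn. Alternatives chosen after seeing the data were a library-set term, protein-coding genes only, removal of mixed cells, clusters from all variable genes, T-cell-like cells without the naive-like cluster, microglia-like cells only, and shares of named cells. The naive-like cluster was the T-cell-like cluster with CCR7 or LEF1 among its leading genes. The library sets were the 4 libraries of HIV donors 1 and 2 and the 3 others, which differed in the share of counts from genes that are not protein-coding. The software was R 4.3.3, python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.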

Results

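Single-cell RNA counts were collected from CSF of HIV donors (n = 3), blood of HIV donors (n = 2) and CSF of uninfected donors (n = 2). Total counts were 3241203, 6839773 and 6084672 in HIV CSF 1, 2 and 3, 7120562 and 7615172 in HIV blood 1 and 2, and 1345901 and 1777626 in uninfected CSF 1 and 2. Cells kept numbered 1217, 2818 and 2547 in HIV CSF, 2609 and 3308 in HIV blood, and 472 and 796 in uninfected CSF. Median counts per kept cell were 1893, 1848 and 1247 in HIV CSF, 1985 and 1352.5 in HIV blood, and 867 and 759 in uninfected CSF. Genes that are neither protein-coding nor mitochondrial took 24.5% and 24.6% of counts in HIV CSF 1 and 2 and 26.0% and 25.3% in HIV blood. The same genes took 42.5% in HIV CSF 3 and 44.7% and 52.7% in uninfected CSF, so the libraries fell into 2 sets. Both blood libraries lay in the first set and both uninfected libraries in the second, and HIV CSF was split between them.

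The series title asks about microglia-like cells in CSF, and their share of cells addresses it. Microglia-like cells, whose 2 clusters had APOE, C1QB and C1QC among their leading genes, made up 6.81% ± 4.09 (SD, n = 3) of HIV CSF cells, 0.320% ± 0.0183 (SD, n = 2) of HIV blood cells and 31.9% ± 13.6 (SD, n = 2) of uninfected CSF cells. B-cell-like cells made up 0.422% ± 0.230 of HIV CSF and 7.97% ± 0.103 of HIV blood. T-cell-like cells made up 59.3% ± 22.5 of HIV CSF, 38.2% ± 18.4 of HIV blood and 13.5% ± 7.89 of uninfected CSF. Monocyte-like cells made up 0.792% ± 0.312 of HIV CSF and 8.72% ± 1.65 of HIV blood, whereas dendritic-like cells made up 2.38% ± 0.468 and 0.438% ± 0.0225. Unnamed clusters held 16.3% ± 24.7, 24.7% ± 24.3 and 27.0% ± 9.10 of cells in HIV CSF, HIV blood and uninfected CSF, and exact permutation p = 0.6 for either contrast. Per library they held 2.14%, 1.81% and 44.8% of HIV CSF, 7.47% and 41.8% of HIV blood, and 20.6% and 33.4% of uninfected CSF. The largest unnamed cluster had CD3D at 3.28 and TRAC at 2.64 per 10000 counts. The largest T-cell-like cluster had 3.34 and 3.68. That unnamed cluster held 1060 cells of HIV CSF 3, and 92 and 255 of uninfected CSF 1 and 2. T-cell-like shares therefore depend in part on cells left unnamed. Another unnamed cluster held 1277 cells of HIV blood 2 and 126 of HIV blood 1. Its leading genes included the B-cell markers MS4A1 and BANK1 and the monocyte markers FCN1, LYZ, S100A8 and S100A9. The B-cell-like, monocyte-like and myeloid-like shares of HIV blood therefore depend in part on unnamed cells as well.

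**Figure D1:**
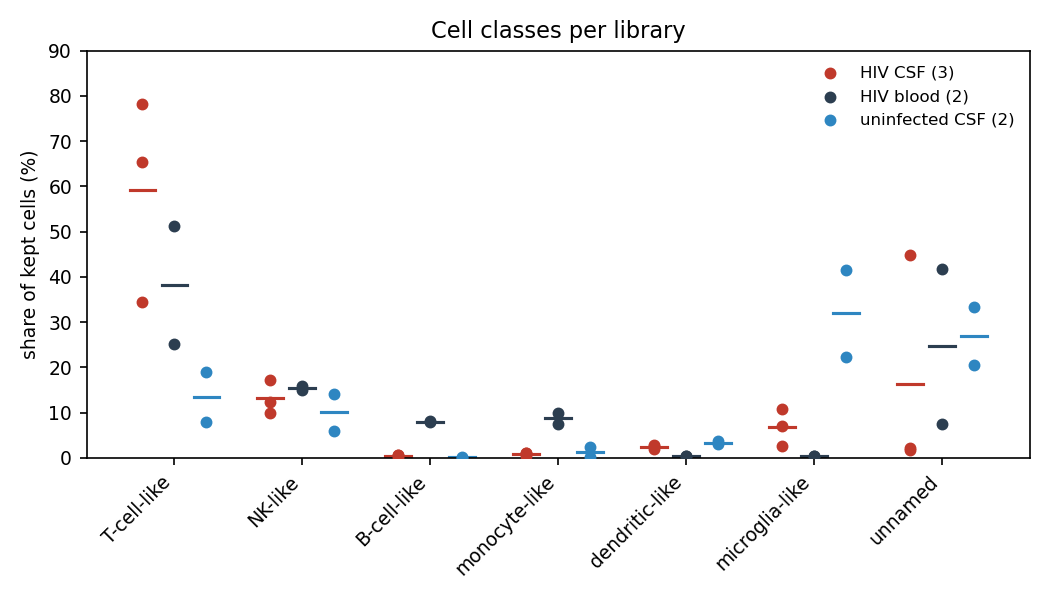
Share of kept cells in percent for 7 cell classes, with 1 dot per library and a line at the mean of HIV CSF (3 libraries), HIV blood (2) and uninfected CSF (2). Microglia-like shares lie at 41.5% and 22.4% in uninfected CSF, above every HIV CSF and blood library.

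Per library, the microglia-like share with its 95% Clopper-Pearson interval was 10.8% (9.08 to 12.6), 2.59% (2.04 to 3.25) and 7.07% (6.10 to 8.13) in HIV CSF, and 41.5% (37.0 to 46.1) and 22.4% (19.5 to 25.4) in uninfected CSF. The difference of means was 6.49 percentage points between HIV CSF and HIV blood (exact permutation p = 0.2) and −25.1 points between HIV CSF and uninfected CSF (exact permutation p = 0.1, the smallest possible). The former was 3.22 to 8.37 points over the other settings and 4.51 to 8.60 with 1 library left out. The latter was −15.6 points without uninfected CSF 1, −8.06 by each cell's own markers and −42.0 among named cells. The class joined a deeper cluster, led by LYVE1 and SEPP1, and a shallower one, led by OLR1 and FSIP1. The shallower cluster gave 22.1 points of the mean share in uninfected CSF and 2.86 in HIV CSF. Its microglia genes stood at 13.9 and 15.6 per 10000 counts in uninfected CSF, against 12.4 and 6.96 in barcodes of at least 100 and under 300 genes. The blood cells of this class were 19 barcodes, and the 11 of them in 1 library held 0 counts of APOE, C1QB and TREM2. The myeloid-like share was 9.97% ± 4.05 in HIV CSF, 9.48% ± 1.61 in HIV blood and 36.5% ± 15.5 in uninfected CSF, with differences of 0.494 points (exact permutation p = 0.9) and −26.5 points (exact permutation p = 0.1). The sign of the first difference depends on how cells were kept and classed, since it was −20.8 points with at least 200 genes per cell and at the lower cluster resolution, −17.2 without mixed cells and −10.4 by each cell's own markers. It was also −0.145 with at least 500 genes, −0.372 among named cells, −1.67 without HIV CSF 1 and −0.643 without HIV blood 2. The second difference was −37.5 to −15.5 points with 1 library left out and −45.3 to −13.1 over the other settings. The T-cell-like share differed by 21.1 points between HIV CSF and blood (exact permutation p = 0.4) and by 45.8 points between HIV and uninfected CSF (exact permutation p = 0.2). The first of these was 8.14 to 34.1 points with 1 library left out and 6.75 to 33.6 over the other settings. The second was 36.4 to 58.3 points with 1 library left out and 20.9 to 51.7 over the other settings. The B-cell-like share differed by −7.55 points between HIV CSF and blood (exact permutation p = 0.1) and by 0.316 points between HIV and uninfected CSF (exact permutation p = 0.3), where uninfected CSF held 1 such cell among 1268 and 0 of 796 cells allow a share of up to 0.377%. The difference between HIV and uninfected CSF was 0.0511 to 0.460 points over the other settings.

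The comparison of HIV CSF with HIV blood asks which transcripts set the fluids apart. A sum over all kept cells can change with the shares of cell classes alone. B-cell-like and monocyte-like shares were lower in HIV CSF than in blood, and microglia-like shares were higher. The mean T-cell-like share was higher too, with overlap between libraries. Changes of markers of these classes were not separated from such differences of makeup. Summed over all kept cells, APOE, TREM2 and C3 rose in CSF, the fatty-acid receptor CD36 fell (−3.25 ± 0.45, adjusted p = 0.0403), and genes of B cells and monocytes fell. The chemokine receptors of tissue-homing T cells CXCR6 (log2 fold change 5.28 ± 0.48, adjusted p = 0.0175), CXCR3 (2.36 ± 0.33, 0.0403) and CCR2 (2.17 ± 0.31, 0.0438) rose, as did the transcription factor MAF (1.71 ± 0.25, 0.0438) and the cytokine-signalling inhibitor CISH (2.40 ± 0.35, 0.0438). The lipoprotein gene APOE rose from 2 counts in blood, a ratio of 551 (152 to 4554), or 304 without HIV CSF 1, with 107.6 ± 102 CPM in CSF. TREM2, a lipid-sensing receptor of microglia, had 0 counts in blood and was at least 73.6-fold higher in CSF (36.8 without HIV blood 1 and 36.9 without HIV blood 2). Complement C3 rose by 4.07 ± 0.47 (adjusted p = 0.0256). The immunoglobulin heavy chain IGHM changed by −5.67 ± 0.42 (adjusted p = 0.0158), the B-cell receptor component CD79A by −4.11 ± 0.35 (0.0158), and the cytotoxic-cell gene FGFBP2 by −5.50 ± 0.62 (0.0245). The monocyte genes FCN1 (−3.61 ± 0.29, adjusted p = 0.0158) and S100A9 (−4.25 ± 0.63, 0.0461) fell as well, and the platelet gene PPBP had 0 counts in CSF and was at least 53.1-fold lower there (30.5 without HIV CSF 2 and 33.2 without HIV CSF 3).

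In all, edgeR passed 85 genes of 18057, 22 higher and 63 lower in CSF, with 1573 at an unadjusted p under 0.05 and 490 by DESeq2. The count was 0 without HIV CSF 2, without HIV blood 1 and without HIV blood 2. It was 3 with only the compared groups and 2 after thinning to equal depth. With only the compared groups, 2 of 33 named genes passed, IGHM and FCN1. There APOE (adjusted p = 0.0785), TREM2 (0.111), C3 (0.0514), CXCR6 (0.0514), CXCR3 (0.0744) and CCR2 (0.0733) did not pass. With donor as a replicate block, CISH (adjusted p = 0.0912), IGJ (0.0648) and PPBP (0.0812) no longer passed.

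Among the fixed lists in all cells, 4 of 8 B-cell markers fell over all genes and 8 adjusted over the list alone, with a median log2 fold change of −3.51 (camera adjusted p = 4.0e-32, and adjusted p = 0.0307 with an estimated correlation). Classical monocyte genes had a median of −2.21 (1.7e-25, and adjusted p = 0.0293 with an estimated correlation), with 5 of 14 lower and CCR2 alone higher, and nonclassical monocyte genes one of −3.11 (1.5e-24, and adjusted p = 0.0384 with an estimated correlation), with 3 of 9 lower. The lists that follow were called only at the preset correlation, and had an adjusted p between 0.0503 and 0.561 with an estimated correlation. They were lower for monocyte markers (median −2.84, adjusted p = 5.9e-22), platelet markers (−5.00, or −4.96 with floors, 3.2e-16), neutrophil markers (−5.11, 3.7e-09), erythroid markers (−4.88, or −4.54 with floors, 0.000507), immediate early and heat shock genes (−1.14, 2.6e-09), inflammatory cytokines (−1.19, 8.0e-08), cytotoxic genes (−0.87, 0.000313) and interferon-stimulated genes (−0.30, 0.0266). They were higher for T memory and migration (0.52, 1.9e-06), complement (1.46, 8.0e-06), border macrophage (2.75, 1.2e-05), T activation and exhaustion (0.73, 6.2e-05), lipid handling (0.28, 0.000768), disease-associated microglia (0.17, 0.00295) and MHC class II (0.70, 0.0206). Of these, 3 of 15 memory and migration genes, 3 of 14 lipid genes and 1 of 11 complement genes rose over all genes, against 5, 4 and 5 adjusted over the list alone. Not called were homeostatic microglia (median 0.34, adjusted p = 0.104), T-cell markers (0.31, 0.0532), naive T (−0.06, 0.0804), regulatory T (0.45, 0.688), cell cycle (−0.55, 0.178), oxidative phosphorylation (0.06, 0.785) and brain and barrier markers (−0.13, 0.785). Iron handling (median −0.44, mean 0.21, tested downward at 0.595) and HIV receptors and restriction factors (median 0.11, mean −0.06, tested downward at 0.860) differed in sign between median, mean and test. With the replicate block, homeostatic microglia (adjusted p = 0.00423), naive T (0.0318) and T-cell markers (0.00441) passed.

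T-cell-like cells were compared between HIV CSF and blood to ask how T cells of the fluids differ. CCR2, a receptor for inflammatory chemokines, rose by 3.63 ± 0.32 on the log2 scale (4.90 ± 1.68 CPM in blood, 59.7 ± 4.88 in CSF). ACTN1, an actin-linking gene high in naive T cells, changed by −2.59 ± 0.25 (60.9 ± 9.37 and 10.1 ± 1.47 CPM). The adjusted p of each was 0.0374. Without the naive-like cluster neither passed, with CCR2 at 2.62 (adjusted p = 0.103) and ACTN1 at −1.45 (0.509). The T memory and migration list had 13 of 15 members above 0 and a median of 1.03, with 1 gene higher over all genes and 7 adjusted over the list alone (camera adjusted p = 8.3e-11, and adjusted p = 0.114 with an estimated correlation). CXCR6, with 3 counts in blood, had a ratio of 61.9 (21.0 to 302), or 34.2 without HIV blood 1 and 117 without HIV blood 2, and LGALS1 (1.91, adjusted p = 0.184) and CXCR3 (2.09, 0.297) did not pass. The naive T list had a median of −0.53 with 1 of 12 lower over all genes and 5 adjusted over the list alone (adjusted p = 1.2e-08, and adjusted p = 0.114 with an estimated correlation). Its members CCR7 (−1.74 ± 0.26, adjusted p = 0.105) and LEF1 (−1.49, 0.204) did not pass. A single naive-like cluster, with CCR7 or LEF1 among its leading genes, held 60.4% of T-cell-like cells in blood and 2.78% in HIV CSF.

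Immediate early and heat shock genes had a median of −0.76 in T-cell-like cells of CSF against blood (camera adjusted p = 4.8e-07, and adjusted p = 0.159 with an estimated correlation), with JUNB at −2.17 (0.106). MHC class II genes (median 0.69, adjusted p = 0.00236, and adjusted p = 0.373 with an estimated correlation) and T activation and exhaustion genes (0.67, 0.0183, and adjusted p = 0.297 with an estimated correlation) were higher. Without the naive-like cluster the medians were 0.35 for MHC class II (adjusted p = 0.219) and 0.23 for T activation and exhaustion, with 5 of 9 above 0 (adjusted p = 0.910). RNA of myeloid cells in these sums also differed by fluid, since monocyte markers had a median of −2.32 (5.9e-09, and adjusted p = 0.159 with an estimated correlation) and complement genes one of 2.66, or 2.28 with floors (0.000389, and adjusted p = 0.114 with an estimated correlation). In those sums C1QB had 35 counts in CSF and 1 in blood, and S100A9 stood at −3.98 (adjusted p = 0.0994). Classical monocyte genes (−1.63, 0.000524, and adjusted p = 0.297 with an estimated correlation) and disease-associated microglia genes (1.12, 0.000571, and adjusted p = 0.230 with an estimated correlation) followed. The lipid handling list differed in sign, with a median of −0.02, a mean of 0.91 and an upward test (0.0400, and adjusted p = 0.297 with an estimated correlation).

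For T-cell-like cells edgeR passed 3 genes of 13047, 2 higher and 1 lower, with 823 at an unadjusted p under 0.05, 169 by DESeq2 and 397 with the replicate block. The count was 70 without HIV CSF 3 and 0 without HIV CSF 1, HIV CSF 2, HIV blood 1 or HIV blood 2. With the block, cytotoxic genes (adjusted p = 2.7e-08, against 0.0737 without it) and HIV receptors and restriction factors (0.0121, against 0.172) also passed, with medians of 0.91 and 0.11 without the block. Without the naive-like cluster the cytotoxic median was 0.03, with 7 of 13 above 0. The same block raised the count from 0 to 2313 in T-cell-like cells of HIV against uninfected CSF, where equal numbers name different donors. Calls gained with the block are therefore uncertain.

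The myeloid-like sums of CSF and blood were compared next, and they mix microglia-like, monocyte-like and dendritic-like cells. APOE, APOC1, TREM2, C1QB, C1QC, MSR1, P2RY12, GPR34 and SLC2A5 are on the marker list that named the microglia-like class. Their rise therefore restates in part how the classes were named and is no separate evidence. HLA-DPB1 and HLA-DRA were among the leading genes of a dendritic-like cluster, so their values are not those of microglia-like cells alone. SPP1, SEPP1, APOE and TREM2 had 0 counts in blood and rose in CSF. SPP1 stood at 28.55, 904 and 1802 CPM in HIV CSF 1, 2 and 3, with adjusted p = 0.0493, or 0.0692 without mixed cells. SEPP1 stood at 1355, 351 and 203 CPM (adjusted p = 0.0156). APOE was at least 402-fold higher, or 267 without HIV CSF 1, 189 without HIV blood 1 and 212 without HIV blood 2. TREM2 was at least 80.0-fold higher, or 37.6 without HIV blood 1 and 42.3 without HIV blood 2. APOE reached 539.9 ± 287 CPM and TREM2 116.0 ± 32.9 in CSF. The hyaluronan receptor LYVE1 (2 counts in blood) had a ratio of 718 (198 to 5937), or 318 without HIV CSF 1. APOC1 (1 count) had a ratio of 369 (65.8 to 14605), or 195 without HIV blood 2. Without HIV blood 1, which held that count, it was at least 57.8-fold higher. The C1q chain genes C1QC (7.75 ± 0.82, adjusted p = 0.00706; 741 ± 556 CPM in CSF, 3.26 ± 0.341 in blood) and C1QB (5.76 ± 0.69, 0.0105; 859 ± 596 and 15.6 ± 5.07) rose, as did C3 (4.62 ± 0.47, 0.00695) and the scavenger receptor MSR1 (4.05 ± 0.68, 0.0257), whereas the complement gene CFP fell (−2.06 ± 0.28, 0.0141). The purine receptor P2RY12 (2.97 ± 0.48, 0.0209) and GPR34 (4.47 ± 0.81, 0.0308), both enriched in resident microglia, rose, and the fructose transporter SLC2A5 was at least 49.2-fold higher, or 31.5 without HIV CSF 1, 23.1 without HIV blood 1 and 26.0 without HIV blood 2. Antigen-presentation genes rose, with HLA-DPB1 at 1.97 ± 0.30 (0.0195; 2601 ± 172 and 665 ± 67.5 CPM) and HLA-DRA at 1.55 ± 0.29 (0.0348).

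Monocyte genes were lower in CSF than in blood myeloid-like cells, with single genes of other lists. S100A8, S100A9, VCAN, FCN1 and CDKN1C are on the marker list that named the monocyte-like class, so their fall restates in part the makeup of the sums. IL8 changed by −5.79 ± 0.83 (adjusted p = 0.0156; 25.7 ± 21.3 CPM in CSF, 1369 ± 548 in blood), the cytidine deaminase APOBEC3A, a restriction factor, by −4.99 ± 0.76 (0.0194), and the nonclassical monocyte gene CDKN1C by −4.80 ± 0.44 (0.00548). The calprotectin genes S100A9 (−4.06 ± 0.36, 0.00548; 344 ± 83.2 and 5751 ± 709.9 CPM) and S100A8 (−3.93 ± 0.41, 0.00706) fell, with VCAN (−3.32 ± 0.45, 0.0141), FCN1 (−3.34 ± 0.39, 0.00896) and the fatty-acid receptor CD36 (−3.64 ± 0.46, 0.0112). NFKBIA, induced by NF-kB, changed by −2.92 ± 0.37 (0.0113), and FOSB (−3.01 ± 0.47), DUSP1 (−2.18 ± 0.38) and ZFP36 (−1.82 ± 0.31) of the immediate early list fell. The interferon-stimulated genes LY6E (−1.54 ± 0.32, 0.0430), IFI6 (−1.42 ± 0.30, 0.0469) and IFIT3 (−1.17 ± 0.25, 0.0491) fell too.

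**Figure D2:**
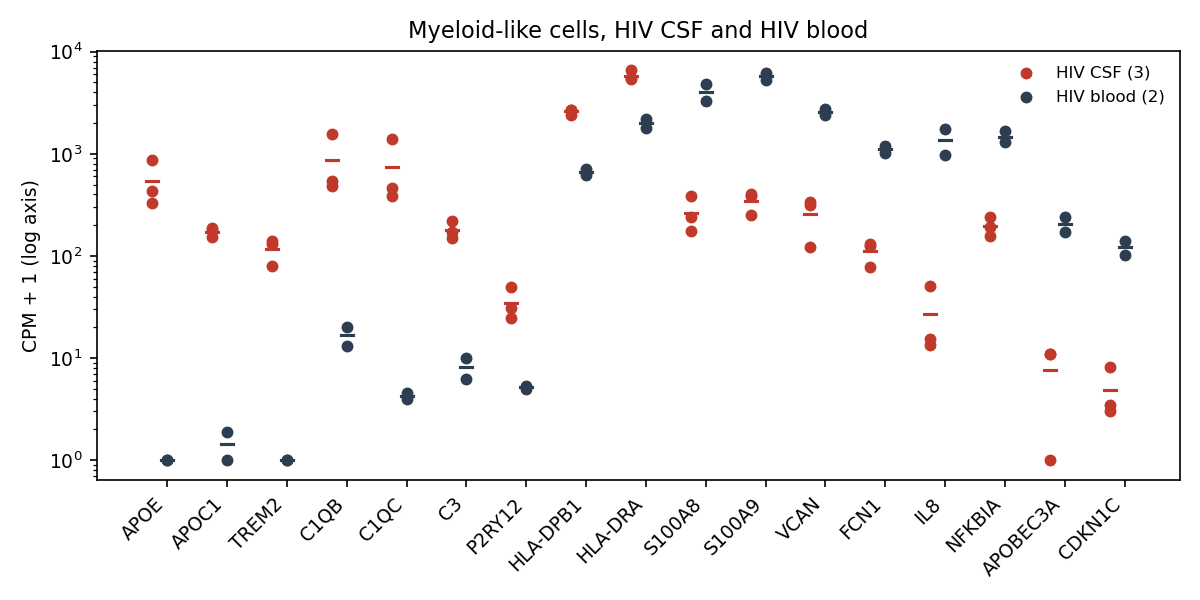
Summed myeloid-like cells: TMM-normalised CPM plus 1 on a log axis for 17 genes, with 1 dot per library of HIV CSF (3) and HIV blood (2). APOE and TREM2 have 0 counts in blood, and S100A9 averages 5751 CPM in blood and 344 in CSF.

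In myeloid-like cells, 299 genes of 10099 passed in edgeR, 157 higher and 142 lower in CSF, and 279 of them were protein-coding. The count was 180 without HIV CSF 1, 21 without HIV CSF 2, 500 without HIV CSF 3 and 0 without HIV blood 1 or HIV blood 2, and 1181 with the replicate block. The makeup of the class differed, since monocyte-like cells were 91.9% of it in blood, whereas microglia-like cells were 64.1% and dendritic-like cells 27.0% of it in HIV CSF.

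Among lists of myeloid-like cells, 5 calls held with an estimated correlation. MHC class II rose with 10 of 10 members above 0 and a median of 1.55, 6 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 1.5e-09, and adjusted p = 0.0376 with an estimated correlation). Classical monocyte (median −2.21, 9 of 13 lower), nonclassical monocyte (−2.79, or −1.34 over 7 genes without mixed cells, 4 of 9 lower) and monocyte marker genes (−2.73, 6 of 8 lower) had adjusted p = 3.3e-19, 4.0e-17 and 8.0e-16, against 0.0137, 0.0449 and 0.0260 with an estimated correlation. T activation and exhaustion genes, which include HLA-DRA and HAVCR2, had a median of 1.48 with 2 of 6 higher (1.3e-05, and adjusted p = 0.0449 with an estimated correlation). The following had an adjusted p between 0.165 and 0.338 with an estimated correlation. Complement (median 2.81, 5 of 10 higher and CFP lower, adjusted p = 1.0e-06), border macrophage (3.41, or 2.36 with floors, 3 of 8 higher, 1.2e-06), lipid handling (1.44, 3 of 11 higher and CD36 lower, 6.5e-06), disease-associated microglia (0.52, 5 of 18 higher and 1 lower, 2.2e-05), homeostatic microglia (0.49, 3 of 8 higher, 0.0128) and cell cycle genes (1.25, 0.00517) were higher. Inflammatory cytokines (−1.77, 3 of 13 lower, 2.7e-09), immediate early and heat shock (−1.24, 5 of 17 lower, 1.0e-07), interferon-stimulated (−0.62, 3 of 23 lower, 1.8e-06), cytotoxic (−0.66, or −1.93 over 7 genes without mixed cells, 2 of 12 lower and GZMK higher, 0.0128) and B-cell marker genes (−1.70, or −2.76 without mixed cells, 0.0128) were lower. Removal of mixed cells moved the median of T-cell markers in these sums from 0.39 to −0.96. With the replicate block, naive T (adjusted p = 0.0151) and oxidative phosphorylation (0.0405) passed and B-cell markers (0.127) did not.

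HIV CSF was compared with uninfected CSF to ask how CSF cells differ with HIV status. In myeloid-like cells, interferon-stimulated genes rose: IFI6, a mitochondrial interferon-response gene, by 2.54 ± 0.40 (adjusted p = 0.0484; 94.2 ± 22.5 CPM in HIV CSF, 16.1 ± 1.80 in uninfected CSF), EPSTI1 by 2.47 ± 0.40 (0.0484; 119 ± 32.9 and 21.1 ± 5.20), the RNA-binding antiviral gene IFIT3 by 2.15 ± 0.36 (0.0484; 51.7 ± 3.24 and 11.4 ± 1.37) and the antiviral GTPase MX1 by 1.82 ± 0.35 (0.0495; 117 ± 25.4 and 33.0 ± 2.36). With library set as a term, the log2 fold changes were 2.61, 2.13, 2.16 and 1.54, with adjusted p = 0.191, 0.196, 0.198 and 0.221. None of these 4 genes passed with only the compared groups (adjusted p of 0.118 for IFI6 and EPSTI1 and 0.119 for IFIT3 and MX1), in microglia-like cells alone (0.0801, 0.0708, 0.0670 and 0.0772), without mixed cells (0.0525, 0.0502, 0.0611 and 0.0530) or with doublets kept. With 1 library left out, none passed unless that library was HIV CSF 3. The list had 23 of 23 members above 0 and a median of 1.61, with 4 higher over all genes and 13 adjusted over the list alone (camera adjusted p = 4.2e-10, and adjusted p = 0.305 with an estimated correlation). IFI44L (2.35, adjusted p = 0.0529), XAF1 (1.72, 0.0572) and ISG15 (0.22, 0.810) did not pass. IFI27, with 3 counts in uninfected CSF, had a ratio of 18.1 (6.06 to 88.7), or 29.9 without uninfected CSF 2.

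Myeloid-like cells of HIV CSF also stood higher in classical monocyte genes (median 0.98, 12 of 13 members above 0 and 3 higher adjusted over the list alone; adjusted p = 0.000888, and adjusted p = 0.305 with an estimated correlation), monocyte markers (0.98, 0.0110, and adjusted p = 0.305 with an estimated correlation) and MHC class II (0.52, 10 of 10 above 0; 0.0228, and adjusted p = 0.373 with an estimated correlation). In microglia-like cells alone the medians were 0.56 for classical monocyte genes (adjusted p = 0.0866), 0.33 for monocyte markers with 5 of 7 above 0 (0.188) and 0.20 for MHC class II (0.188), so these lists were not called there. The central 95% of medians of random coding lists matched on level reached 0.47, 0.48 and 0.40 in all myeloid-like cells, in the same order. VCAN (1.96, adjusted p = 0.0643), LYZ (1.07, 0.0887) and HLA-DPB1 (0.79, 0.144) did not pass. Microglia lists were not called: homeostatic microglia had a median of 0.42 (adjusted p = 0.305), disease-associated microglia 0.13 (0.305), complement 0.56 (0.278), lipid handling 0.39 (0.305) and border macrophage 0.49 (0.658), with C1QB at 0.80 (0.450), APOE at 0.39 (0.705) and TREM2 at −0.05 (0.958). With library set as a term the medians were −0.26 for homeostatic microglia (3 of 8 above 0), 0.11 for disease-associated microglia, 0.13 for complement, −0.10 for lipid handling (4 of 11) and −0.89 for border macrophage (2 of 8). Microglia-like cells were 64.1% of these cells in HIV CSF and 87.6% in uninfected CSF, and monocyte-like cells 8.92% and 2.70%. All 12 monocyte-like cells of uninfected CSF and 24 of 50 in HIV CSF lay in 1 cluster that also carried T-cell genes. Its CD3D and CD2 stood at 1.83 and 2.56 per 10000 counts, against 0.131 and 0.192 in the largest monocyte-like cluster. Some of these cells may therefore be mixed. Erythroid markers had a median of −6.48, or −6.09 with floors (0.0236, and adjusted p = 0.570 with an estimated correlation).

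In that comparison edgeR passed 145 genes of 10099, 11 higher and 134 lower, with 2193 at an unadjusted p under 0.05 and 787 by DESeq2. Of the 145 genes 127 were not protein-coding, and 124 of these were lower in HIV CSF. The median log2 fold change was 0.25 over protein-coding genes and −1.72 over other genes, along the split of the library sets. Uncertain genes among the lowest were the pseudogenes TPT1P5 (−5.33 ± 0.66) and FTH1P16 (−3.71 ± 0.68), the mitochondrial-like gene MTRNR2L6 (−4.01 ± 0.69) and several clone-named genes. IL1RAPL1, a protein-coding synapse gene, changed by −4.13 ± 0.57 (adjusted p = 0.0484). The count was 0 without HIV CSF 1, without HIV CSF 2 and without uninfected CSF 2, 32 without uninfected CSF 1 and 2020 without HIV CSF 3, when the HIV and uninfected libraries lie wholly in different sets, and 0 with library set as a term.

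T-cell-like cells of HIV and uninfected CSF differed in the same list, with 23 of 24 interferon-stimulated genes above 0, a median of 1.37, or 1.16 with floors, and 10 higher adjusted over the list alone (camera adjusted p = 6.5e-06, and adjusted p = 0.605 with an estimated correlation). EPSTI1 (2.02, adjusted p = 0.185) and IFI6 (1.81, 0.185) did not pass, and IFIT1 had 0 counts in uninfected CSF and 81 in HIV CSF. The lower bound of its fold was 1.53, but 0.606 without uninfected CSF 1 and 0.944 without uninfected CSF 2. The median log2 fold change was 0.40 over protein-coding genes and −1.31 over others, so a list of coding genes lies above 0 without a change of its own. For the interferon-stimulated list, the central 95% of medians of random coding lists matched on level reached 0.66, below its median. Oxidative phosphorylation genes had 20 of 20 members above 0 and a median of 0.63 (0.000603, and adjusted p = 0.719 with an estimated correlation), where the central 95% of random coding lists matched on level reached from 0.29 to 0.61. Cytotoxic genes had a median of 0.82, or 0.80 with floors (0.0304, and adjusted p = 0.719 with an estimated correlation), where random lists reached 0.74. With library set as a term the cytotoxic median was 0.14, with 7 of 13 above 0 (adjusted p = 0.874). The makeup of T-cell-like cells differed by library. The cluster led by GZMK, with CD8A among its leading genes, held 41.2%, 30.8% and 3.54% of them in HIV CSF and 25.6% and 3.17% in uninfected CSF, and the largest T-cell-like cluster 22.9%, 25.6% and 84.1%, and 32.2% and 95.2%. No gene passed: edgeR gave 0 of 13047, with 2675 at an unadjusted p under 0.05 and 514 by DESeq2. Without HIV CSF 3, when the groups lie wholly in different library sets, the count was 2093.

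Over all kept cells, interferon-stimulated genes had 24 of 24 members above 0 and a median of 1.34, with 17 higher adjusted over the list alone (camera adjusted p = 2.0e-10, and adjusted p = 0.0434 with an estimated correlation). EPSTI1 (2.02 ± 0.34, adjusted p = 0.0995; 80.5 ± 7.68 and 19.8 ± 6.90 CPM) and IFITM1 (1.53, 0.0995) did not pass. T-cell genes went with the higher T-cell-like share of HIV CSF, with naive T at a median of 1.16 (1.3e-05, and adjusted p = 0.385 with an estimated correlation), T-cell markers at 0.95 with 9 of 9 above 0 (0.000233, and adjusted p = 0.385 with an estimated correlation) and CCR7 at 73.5 ± 9.34 CPM in HIV CSF and 18.3 ± 1.78 in uninfected CSF (adjusted p = 0.0995). Memory and migration (0.45, 0.0180), HIV receptors and restriction factors (0.46, 0.0457), cytotoxic (0.77, 0.00769), oxidative phosphorylation (0.42, 0.00769) and erythroid marker genes (−6.88, 0.00241) were called at the preset correlation, and had adjusted p between 0.385 and 0.767 with an estimated correlation. The central 95% of medians of random coding lists matched on level reached 0.64 for memory and migration, 0.65 for HIV receptors and restriction factors and 0.63 for oxidative phosphorylation, so these 3 medians lay within the shift of all coding genes. It reached 0.67 for cytotoxic genes, 0.67 for naive T, 0.72 for T-cell markers and 0.59 for interferon-stimulated genes. HBB (−6.21, adjusted p = 0.112) stood at 7.99 ± 11.2 CPM in HIV CSF and 566 ± 607.6 in uninfected CSF. Here edgeR gave 0 genes of 18057, with 5065 at an unadjusted p under 0.05 and 1676 by DESeq2, and the median log2 fold change was 0.33 over protein-coding genes and −1.21 over others. Without HIV CSF 3, again with the groups in different sets, the count was 3887, and without uninfected CSF 1 it was 2.

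**Figure D3:**
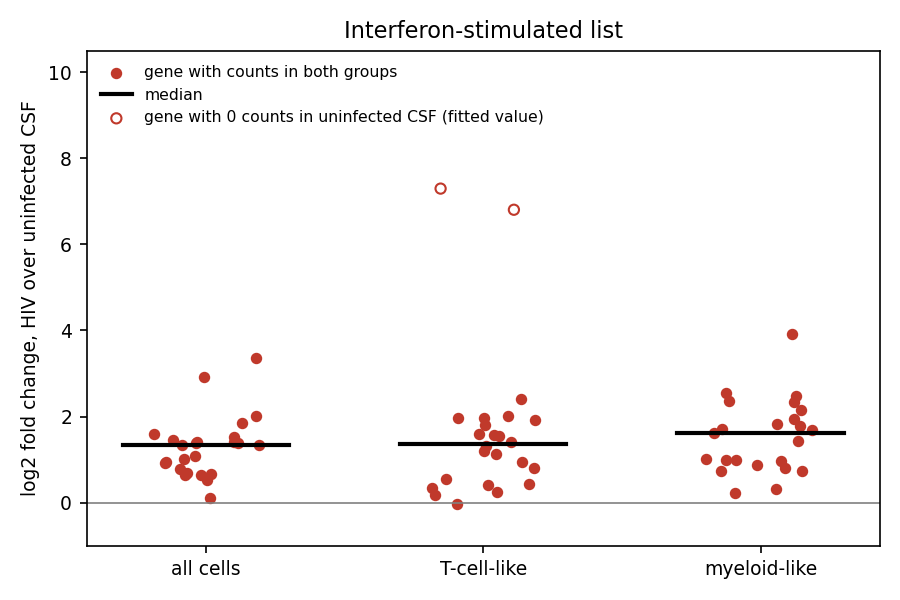
Log2 fold change of HIV over uninfected CSF for the interferon-stimulated list in all cells, T-cell-like cells and myeloid-like cells; bars are medians and open circles are genes with 0 counts in uninfected CSF, whose fitted values are no bounds. The medians are 1.34, 1.37 and 1.61.

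Levels within microglia-like cells, which were not tested, show what RNA this class carried in either CSF group. C1QB stood at 14.99 ± 7.21 per 10000 counts in HIV CSF (n = 3) and 5.06 ± 0.148 in uninfected CSF (n = 2), APOE at 10.1 ± 4.47 and 4.28 ± 0.476, and TREM2 at 2.09 ± 0.158 and 1.24 ± 0.376. The class lay in different clusters by library, since the deeper cluster held 111 of 131, 50 of 73 and 24 of 180 microglia-like cells in HIV CSF and 70 of 196 and 39 of 178 in uninfected CSF. Microglia genes together, among them no homeostatic microglia gene, stood at 83.7, 69.9 and 61.2 per 10000 in the deeper cluster of HIV CSF. In that of uninfected CSF they stood at 35.2 and 30.4. In the shallower cluster they stood at 32.6, 22.2 and 13.8 in HIV CSF and 13.9 and 15.6 in uninfected CSF. In barcodes of at least 100 and under 300 genes the values were 7.70, 2.74 and 2.46, and 12.4 and 6.96. In T-cell-like cells they were 0.296, 0.0695 and 0.225, and 1.21 and 0.224, and APOE stood at 0.0331 and 0.130 per 10000. P2RY12 stood at 0.327, 1.01 and 0.399 in HIV CSF and 0.464 and 0.371 in uninfected CSF, and TMEM119, a marker of resident microglia, had 14 and 4 counts in all. The antigen-presentation gene CD74 stood at 42.2 ± 5.19 and 31.3 ± 10.2. Median depth of cells differed between the groups, and in HIV CSF the level of C1QB spread more between libraries than in uninfected CSF. Protein-coding genes took 67.7%, 65.3% and 53.5% of counts in kept cells of HIV CSF, against 49.15% and 40.9% in uninfected CSF. These levels are not adjusted for that difference, which lowers coding genes in uninfected CSF. In the normalised myeloid-like sums, APOE and TREM2 did not pass between these groups.

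**Figure D4:**
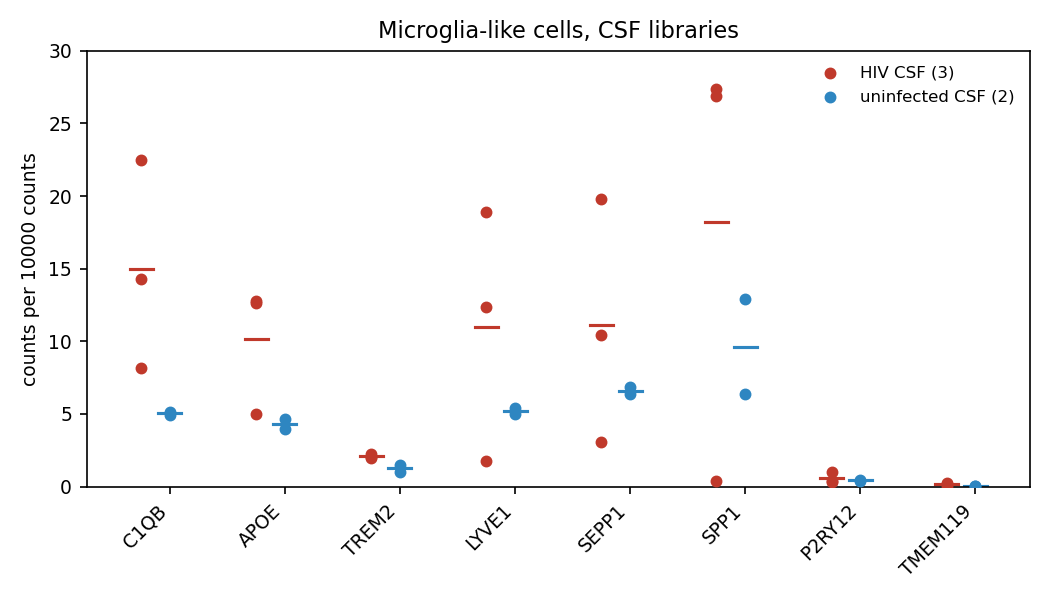
Counts per 10000 counts of microglia-like cells for 8 genes, with 1 dot per library of HIV CSF (3) and uninfected CSF (2). C1QB averages 14.99 in HIV CSF and 5.06 in uninfected CSF, and TMEM119 lies near the floor in every library. Levels are not adjusted for the lower share of protein-coding counts in uninfected CSF.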

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

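All tests in this part were chosen after the results they address were seen. Barcodes with at least 100 and under 300 genes lay below the limit of kept cells, and those from 200 genes entered only 1 alternative. They were set apart because T-cell RNA in all HIV CSF libraries, and hemoglobin RNA in 1, stood above its level in uninfected CSF. T-cell genes reached 33.0, 38.6 and 20.2 per 10000 counts in 403, 760 and 1993 such barcodes of HIV CSF 1, 2 and 3, against at most 11.7 in uninfected CSF. In such barcodes of HIV blood 1 and 2 they stood at 20.4 and 20.7, so HIV CSF 3 did not exceed blood. Hemoglobin genes reached 190.6 per 10000 counts in HIV CSF 1, against 43.6 and 48.3 in uninfected CSF and 0 in HIV CSF 2 and 3. HIV blood 1, which carries the same donor number as HIV CSF 1, stood at 185.6, and HIV blood 2 at 0.474. No explanation of these values was tested.

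The microglia-like share was lower in every HIV CSF library than in either uninfected CSF library, by 25.1 points on average. The difference was −8.06 points by each cell's own markers and −15.6 without uninfected CSF 1. More T cells in the denominator are not enough for this in the class as a whole, since the number of microglia-like cells per dendritic-like cell, which holds no T cells, still differed by −6.47 (3.001 against 9.47) without overlap. For the deeper microglia-like cluster alone this ratio overlapped, at 3.58, 0.649 and 0.511 against 4.12 and 1.63, so there that explanation stays open. The shallower of the microglia-like clusters may carry much of it. In the deeper cluster alone the difference was −5.92 points, and shares of 0.942 to 9.12% in HIV CSF overlapped 4.90 and 14.8% in uninfected CSF. Library set cannot be told apart from HIV status, since the second set holds 1 HIV library, with a difference of −24.9 points there; a difference by HIV status stays open as well.

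Interferon-stimulated genes were higher in HIV than in uninfected CSF in myeloid-like cells, with a median log2 fold change of 1.61. A shift of all protein-coding genes is not enough for this, since the upper end of the central 95% of medians of 10000 random lists matched on level was 0.46. A larger share of monocyte-like and dendritic-like cells is not enough either, since the median in microglia-like cells alone was 1.76 (camera adjusted p = 1.5e-11 at the preset correlation). With an estimated correlation no list of this comparison was called in myeloid-like cells, and microglia-like cells alone were not tested that way. The list was not examined in the deeper and shallower microglia-like clusters apart, so their differing makeup by library stays open. Library set cannot be told apart from HIV status, because 1 HIV library lies in the second set, although the median with library set as a term was 1.22. An interferon response that goes with HIV status may underlie the pattern and stays a hypothesis.

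Memory and migration genes were higher in CSF than in blood in T-cell-like cells, with a median of 1.03. RNA of myeloid cells in these sums is not enough for this. By the markers of microglia-like, monocyte-like and dendritic-like cells it was at most 1.92% of any CSF sum. With that RNA taken off the CSF sums alone, the median log2 ratio of mean CPM was 1.13, against 1.15 before. A larger share of naive-like cells in blood may explain most of the median, which was 0.18 without the naive-like cluster. Its camera adjusted p was 0.000883 there at the preset correlation. With an estimated correlation no list of this comparison was called in T-cell-like cells. A difference within memory cells of either fluid stays open for the rest.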

How the results depend on the processing

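The library-set term, protein-coding genes only, removal of mixed cells, clusters from all variable genes, T-cell-like cells without the naive-like cluster, microglia-like cells only and shares of named cells were chosen after the results were seen; the other alternatives were planned. Among 110 named gene results with 2135 values, 0 changed sign, and 1460 values passed 5% and 675 did not. Shares kept their direction in 120 values and reversed in 8, all of the myeloid-like share of CSF against blood. That difference, 0.494 points, was −0.145 with at least 500 genes per cell, −20.8 with at least 200, −10.4 by each cell's own markers, −20.8 at the lower cluster resolution, −17.2 without mixed cells, −0.372 among named cells, and −1.67 to 2.34 with 1 library left out; the cause was not tested. The microglia-like difference of HIV against uninfected CSF lay between −42.0 and −8.06 points over the other settings and between −34.7 and −15.6 with 1 library left out.

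Counts of changed genes moved by more than 1.5 times in 66 values and not in 53. For CSF against blood the count in all cells (85) was 643 without a gene filter, 3 with the compared groups only, 458 among protein-coding genes, 2 after thinning, 490 by DESeq2 and 0 to 122 with 1 library left out. In T-cell-like cells (3) it was 287 without a filter, 397 with the replicate block, 68 with the library-set term, 187 among protein-coding genes, 169 by DESeq2, and 0 to 70 with 1 library left out. There it was 0 with the compared groups only, after thinning, with at least 500 genes, by own markers, without mixed cells and without the naive-like cluster. In myeloid-like cells (299) it was 1004 without a filter, 1181 with the block, 503 with the set term, 807 among protein-coding genes, 109 after thinning, 198 with at least 200 genes, 177 by own markers, 168 without mixed cells, and 0 to 500 with 1 library left out.

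For HIV against uninfected CSF the count in all cells (0) was 2540 without a filter, 3610 with the replicate number as a block, although the numbers name different donors, 64 among protein-coding genes, 1676 by DESeq2 and 0 to 3887 with 1 library left out. In T-cell-like cells (0) the same settings gave 1750, 2313, 15, 514 and 0 to 2093. In myeloid-like cells (145) they gave 1858, 1805, 18, 787 and 0 to 2020, with 296 after thinning. There it was 0 with the compared groups only, the set term, at least 500 or 200 genes, doublets kept, own markers, mixed cells removed and microglia-like cells only.

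With an estimated correlation the lists called for CSF against blood were 3 of 18 in all cells, 0 of 10 in T-cell-like cells and 5 of 16 in myeloid-like cells, and for HIV against uninfected CSF 1 of 8, 0 of 3 and 0 of 5. For the latter contrast the set term gave 15 lists in all cells and 10 in myeloid-like cells, the block 5 in all cells, and microglia-like cells only gave 2. A library left out leaves fewer samples, a 1-library arm is assumed to vary like the other groups, and coding genes alone mean fewer tests; otherwise the cause was not tested. The donor block changed no call among named genes and lists of CSF against blood other than those given beside the results. Depth limits uninfected T-cell-like sums most, at 222822 and 346795 counts.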

Other observations

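The permutation tests in this part were chosen after the classes were seen. NK-like cells made up 13.2% ± 3.72 of HIV CSF, 15.4% ± 0.585 of HIV blood and 10.1% ± 5.84 of uninfected CSF (exact permutation p = 0.5 for either contrast). They differed by cluster: the cluster led by FGFBP2, a gene of mature cytotoxic NK cells, held 296 and 361 cells in blood and 0, 5 and 1 in HIV CSF. The cluster led by the chemokine gene XCL1 held 210, 342 and 253 cells in HIV CSF and 116 and 134 in blood. It also carried T-cell genes, with CD3D at 4.18, TRAC at 3.78 and CD8A at 3.12 per 10000 counts. The T-cell-like cluster led by GZMK had 5.06, 4.84 and 4.48, and the FGFBP2-led cluster 3.65, 2.13 and 3.07. The NK-cell gene KLRF1 stood at 0.463 in the XCL1-led cluster and 2.93 in the FGFBP2-led one. The NK-like shares may therefore include T cells, which the T-cell-like shares and sums leave out. Neutrophil-like cells were 4.18% (109 cells) and 0.242% (8 cells) of HIV blood 1 and 2 and 0% of HIV CSF, and erythroid-like cells were 11.4% ± 8.36 of uninfected CSF and 0.0810% of HIV CSF (exact permutation p = 0.1 for each). Plasma-cell-like cells, whose cluster was also led by the proliferation genes MKI67 and TOP2A, were 0.270% of HIV CSF and 1.03% of HIV blood (exact permutation p = 0.1). Cells like plasmacytoid dendritic cells were 0.498% of HIV CSF and 0.281% of HIV blood (exact permutation p = 0.8).

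Microglia-like cells carried genes of border macrophages as well as of resident microglia. LYVE1 stood at 18.9, 12.4 and 1.78 per 10000 counts in HIV CSF 1, 2 and 3 and at 5.43 and 4.99 in uninfected CSF. SEPP1, a selenium carrier, stood at 19.8, 10.47 and 3.10, and 6.82 and 6.37, so for both genes HIV CSF 3 lay below both uninfected libraries. The border macrophage list summed to 55.0, 30.3 and 8.22 per 10000 in HIV CSF and 16.9 and 15.04 in uninfected CSF, against 14.4, 14.7 and 5.06, and 6.79 and 5.60, for homeostatic microglia. SPP1, the gene for osteopontin, stood at 0.400, 26.9 and 27.4 per 10000 in HIV CSF and 6.35 and 12.9 in uninfected CSF. SALL1, a transcription factor of microglia, had 0 counts in microglia-like cells of HIV CSF and 2 in those of uninfected CSF, and the scavenger receptor MRC1 had 8 and 9. Interferon-stimulated genes summed to 27.4, 24.5 and 17.1 per 10000 in HIV CSF and 6.88 and 5.90 in uninfected CSF. None of these levels and sums is adjusted for the lower share of protein-coding counts in uninfected CSF.

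Lists that differed in sign between median, mean and test, none of them called, were also present in other comparisons. In myeloid-like cells of CSF against blood these were iron handling (median −0.31, mean 0.56, tested downward) and memory and migration (median 0.14, tested downward). In myeloid-like cells of HIV against uninfected CSF they were inflammatory cytokines (median −0.13, mean 0.06) and iron handling (median −0.12, mean −0.04), both tested upward.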
